A study of Streptococcus mutans UA159 with 8 samples.

How the data were processed

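Total RNA came from biofilms of Streptococcus mutans UA159 grown for 8 h in polystyrene wells with or without 0.25 µg/ml carolacton, from an initial OD600 of 0.01. Per the labels' protocols, the RNA was labelled directly with Cy3 or Cy5 and hybridised to a custom 2-colour Agilent array. Per the design text, 4 biological replicates were each hybridised a second time with the dyes swapped, which gave 8 arrays. Each array held carolacton RNA in one channel and untreated RNA of the same replicate number in the other.

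The deposited scanner output holds one row per spot with linear intensity values, which the authors' scanner software wrote before any normalization between arrays. Per the file headers, spots were quantified with Agilent Feature Extraction 10.5.1.1, which also gave a log10 ratio of Cy5 over Cy3 and flags for signal above background, saturation and outlier spots. The deposited intensity values are rounded to few significant digits. The deposited value table was read as log2 ratios and has a mean of 0 on each array. Set against the scanner's log10 ratios of the same spots, its columns correlated at 0.928 to 0.979 across spots once both were turned to carolacton over untreated, with slopes of 2.26 to 2.66 and column medians of -0.14 to -0.03. Its centring and direction were taken from that comparison. These slopes lie below that of an exact conversion from log10 to log2, so the log2 scale is assumed and sizes from this table depend on it. Its background correction and normalization are not given in the sources used here. The submitters' processing notes name limma, without a version.

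The array carries 15744 spots, of which 536 are controls. The gene probes number 5856, 45 to 60 bases long, for 1952 genes. A further 1177 probes lie between genes, and 18 probes are for 6 sequences that are not from this organism. Gene coordinates are those of the array annotation, on the sequence AE014133.1. Locus tags of 1833 of the 1952 genes matched the RefSeq table of assembly ASM746v2, which was used for names only. A symbol was taken from that table first, then from the array annotation, then from the gene lists fixed beforehand. This last source applies to the members matched by locus tag, such as cipB, nlmA, nlmB, cclA and vicR. One array symbol was overruled: covR stands on SMU.1517, whose description names VicR, so covR was taken by its own locus tag. The array names the F-type ATPase genes by an older scheme, so their locus tags are given.

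Intensities (mean signal and median local background) were background-corrected with normexp at an offset of 50, and log2 ratios were normalized by loess within each array with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Spots that the scanner called outliers, 1.79 to 2.93% of spots per array, were left out. Saturated spots were kept. Tables were read with the R package data.table, version 1.17.8. Spots of a probe were averaged and then probes of a gene. In 14 genes the probes lay more than 1 log2 unit apart, and 6 genes share a probe sequence with another gene and are uncertain. A probe entered if it was well above background in the carolacton channel on at least 4 of 8 arrays or in the untreated channel on at least 4 of 8. This left 1902 genes; 38 had no such probe and 12 were lost to outlier spots. Log2 ratios were turned to carolacton over untreated, and both dye orientations of a replicate were averaged, so that n is 4. Each gene's ratio was tested against 0 with lmFit and eBayes and the p-values were adjusted by the Benjamini-Hochberg method at 0.05. A second count took an absolute log2 ratio of at least 1. All adjusted p-values of single genes are from this limma fit, two-sided. Errors are SDs between the 4 replicates unless stated. The dye effect of a gene is its log2 ratio of Cy5 over Cy3 that is common to both orientations, tested in the same way on the differences between orientations.

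The numbering pairs the arrays by design. The deviations of same-numbered arrays from the mean of their orientation correlated at 0.85 to 0.935 across genes in the 4 replicates. All 8 arrays lay on 1 slide, with the dye orientations in its rows and the replicates in its columns, so slide could not serve as a block. The precision is limited by the 4 biological replicates, since both arrays of a replicate hold RNA of that same replicate. Median mean signals were 3590 to 9890 in Cy3 and 5880 to 16600 in Cy5 against local background medians of 54 to 100. Negative control spots gave 834 to 1390, above the local background. Between 79.4 and 93.8% of spots per channel were well above background and 0.848 to 12.2% were saturated. For a gene saturated on every carolacton array, only a lower bound of its fold is given, and only where no untreated array was saturated, as the difference of mean log2 intensities after Aquantile normalization between arrays. For genes near saturation in both channels, ratios are compressed towards 0.

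Before the data were examined, 29 gene lists, the fits, the alternatives and the rule for named genes were fixed. The rule took the 15 largest rises and 15 largest falls among genes with an adjusted p under 0.05 and the same sign in all 4 replicates, up to 4 members of each list with the smallest adjusted p, and 17 genes whatever their values (pknB, pppL, vicR, vicK, vicX, comC, comD, comE, comX, cipB, gtfB, gtfC, gtfD, ftsZ, divIVA, atlA and folD). Adjacent named loci that changed the same way are described together. The 28 lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. Where a list symbol matched a gene of another function this is said beside it.

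The procedure was tested on simulated arrays of these 1902 genes for the comparison of carolacton with untreated biofilms, with 200 genes changed. At 1.5-fold 86.6% were recovered, at 2-fold 97% and at 4-fold 100%, and 7 unchanged genes were called. These rates are for 200 changed genes, whereas the fit of the real arrays called 1447. In a simulation that took the estimated log2 ratios as the true ones, 1459 genes were called, 99.8% of them with the true sign. For this share the true ratios were first shifted by the median difference between estimated and true ratios. The simulation was revised once, since its first form had no unspecific signal and missed its own tolerance for the estimated sizes. With 200 genes changed, the estimated log2 ratio was 0.962 to 0.968 times the true one in the median. Alternatives covered the background correction, the normalization within and between arrays, the filter on dim probes, the probe summary, the replicate block, single dye orientations, separate channels, the deposited value table, the prior variance, each replicate left out, and a threshold of 0.01. Removing the trend of log2 ratios with chromosomal position (loess on the distance from the origin, span 0.5, in each replicate) and leaving out the dimmest array were added after seeing the data. The origin was placed at coordinate 1, next to dnaA.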

Results

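Carolacton is a secondary metabolite of the myxobacterium Sorangium cellulosum that damages biofilms of the caries bacterium Streptococcus mutans. The series measured RNA levels in S. mutans UA159 biofilms grown for 8 h with 0.25 µg/ml carolacton against untreated biofilms, in 4 biological replicates with a dye swap of each, on 8 arrays of 2 colours. The comparison asks which genes differ in RNA level between treated and untreated biofilms. Of 1952 genes on the array, 1902 were measured. The 4 replicates correlated with one another at 0.843 to 0.991 across genes, and both dye orientations of a replicate at 0.964 to 0.981.

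Carolacton changed the relative RNA level of most genes. Normalization within arrays centres log2 ratios near 0, so higher and lower are relative to the typical gene. Absolute RNA amounts were not measured. The limma fit called 1447 of 1902 genes (76.1%), of which 667 were higher and 780 lower with carolacton, and 455 genes did not pass. At least 2-fold changes were found for 377 genes, 217 higher and 160 lower. At least 4-fold, 58 genes rose and 6 fell. The 58 include all 24 adjacent measured genes from SMU.191c to SMU.217c (lowest log2 ratio 2.45) and genes of the mutacin loci, so they are not 58 separate responses. Some lie near the replication origin, such as mnmG, whose 2.18 became 1.31 with the position trend subtracted. Of the 1447 genes, 1416 had the same sign in all 4 replicates, and the median SD between replicates was 0.16 on the log2 scale. With the deposited value table, which is centred on its mean, 35.7% of 1433 calls were higher, against 46.1% here, and the median gene stood at -0.17 in place of -0.03. Rises that were over 1.5 times smaller in that table included comC (0.40), comD (0.47), comE (0.39), fabM (0.19), accA (0.37), glgP (0.37), glgA (0.23), mubT (0.44), mubG (0.52) and mleP (0.17), and falls that were over 1.5 times larger included dltB (-0.54), pppL (-0.52), pknB (-0.46) and folD (-0.36).

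**Figure D1:**
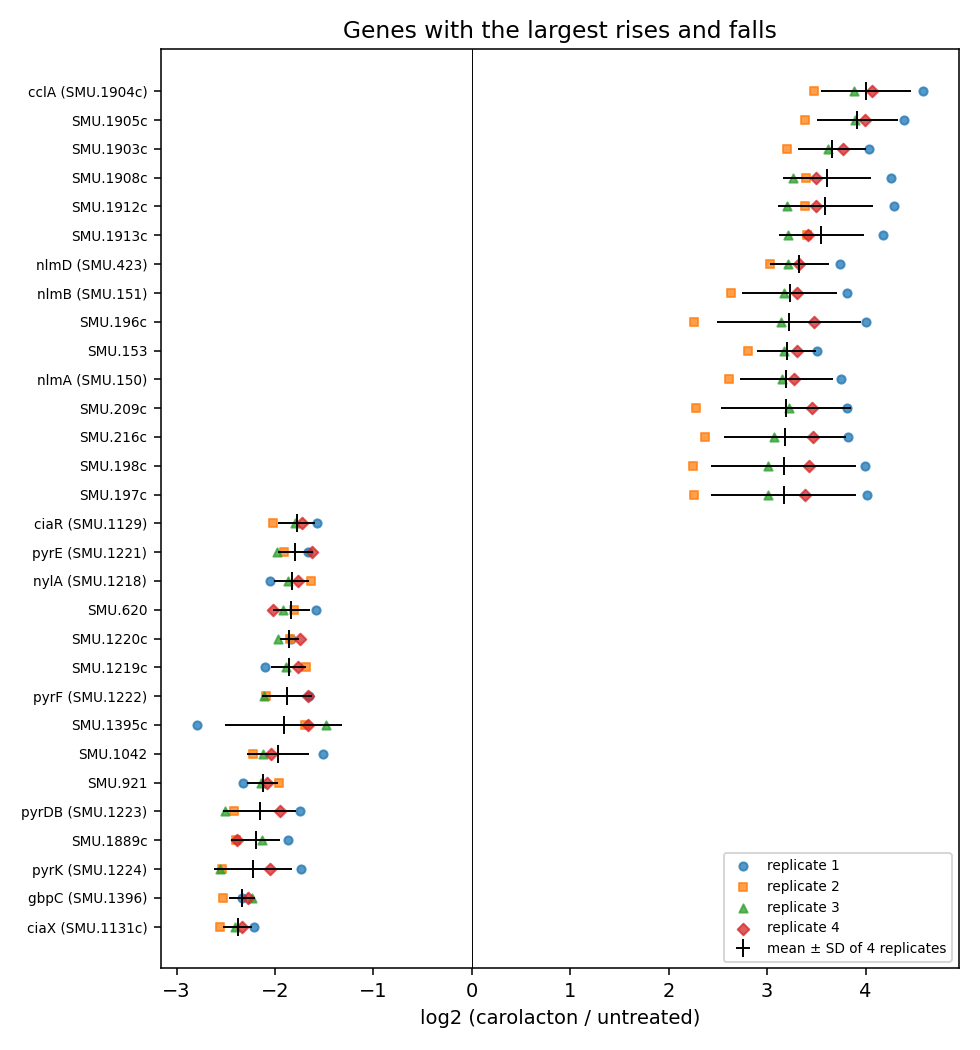
The log2 ratio of carolacton over untreated RNA (x axis) of the 15 genes with the largest rises and the 15 with the largest falls (y axis), with one symbol per replicate and the mean ± SD of 4 replicates in black. The mean rises lie between 3.17 and 4.00 and the falls between -2.38 and -1.78, and all 4 replicates of each gene lie on the same side of 0.

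The largest rises were in and around genes of mutacins, the bacteriocins of S. mutans, and their immunity proteins. At SMU.1902c to SMU.1914c (coordinates 1787777 to 1794741) 11 neighbouring genes rose, with a median log2 ratio of 3.55. In this region cclA (SMU.1904c) rose 16.01-fold (log2 ratio 4.00 ± 0.46, SD, n = 4, adjusted p = 4.89e-05), SMU.1905c, a putative bacteriocin secretion protein, 15.1-fold (3.91 ± 0.41), SMU.1903c 12.6-fold (3.66 ± 0.35), SMU.1908c 12.2-fold and SMU.1912c 12.1-fold. The fixed lists hold cclA under competence and not under mutacins. SMU.1913c, annotated as an immunity protein, rose 11.7-fold (3.55 ± 0.43). The carolacton channel was saturated on 7, 6 and 7 of 8 arrays for SMU.1908c, SMU.1912c and SMU.1913c, so that their measured folds are compressed and their rank among the rises is not settled. The gene at the end of this region, cipB (SMU.1914c), which encodes mutacin V, was saturated on all 8 arrays in the carolacton channel and on 4 of 8 in the untreated channel, so that no fold is given. Its compressed log2 ratio was 1.58 (adjusted p = 0.000118), with 3.10 on the arrays with carolacton in Cy5, 0.06 on those with carolacton in Cy3 (adjusted p = 0.278) and 1.02 with the trend along the chromosome subtracted. Genes nlmA and nlmB (SMU.150 and SMU.151), which encode the peptides of mutacin IV, rose 9.16-fold (3.20 ± 0.47) and 9.37-fold (3.23 ± 0.48), their neighbour SMU.153 rose 9.18-fold, and nlmD (SMU.423) rose 10.03-fold (3.33 ± 0.30). Of 22 measured mutacin and immunity genes, 15 rose and 6 fell, among the latter SMU.1889c, which fell 4.59-fold (log2 ratio -2.20 ± 0.25). The list median was 2.89 (camera adjusted p = 0.013), with adjusted p = 0.689 under an estimated correlation. The other 5 falls were smaller, among them cipI, the immunity gene of mutacin V, at -0.65. The genes SMU.1906c and SMU.1910c, saturated on all 8 arrays in the carolacton channel, were at least 4.10-fold and 6.44-fold higher (adjusted p = 6.96e-05 and 0.000114).

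A second block of rises had no list of its own. The 24 adjacent measured genes from SMU.191c to SMU.217c (coordinates 192029 to 209913), annotated as an integrase, a transfer protein, conjugative transposon proteins and hypothetical proteins, all rose, with a median log2 ratio of 3.05 and a range from 2.45 to 3.22. Among them SMU.196c rose 9.31-fold (3.22 ± 0.73), SMU.209c 9.14-fold, SMU.216c 9.06-fold and SMU.197c 8.98-fold, and SMU.198c rose by a log2 ratio of 3.17 ± 0.74. The block's median was 3.79 in replicate 1 and 2.23 in replicate 2, with replicates 3 and 4 at 2.92 and 3.30. The 92 other genes within 50 kb had a median of 0.48.

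Log2 ratios also varied with the position of a gene on the circular chromosome. Among 366 genes within 200 kb of the replication origin the median log2 ratio was 0.61, and 68.3% rose while 5.74% fell. Among 402 genes more than 800 kb from it the median was -0.61, and 12.2% rose while 72.6% fell. Across genes, which are not independent replicates, the log2 ratio and the distance from the origin had a Spearman rho of -0.58, and in each replicate a rho between -0.63 and -0.49. With this trend subtracted, an alternative chosen after seeing the data, 1354 genes were called, 563 higher and 791 lower, and 267 changed at least 2-fold. Of the 1447 calls 940 were kept with their direction, and 115 were called in the opposite direction. The trend stood at 0.55 to 0.57 for the named genes from SMU.1903c to cipB, at 0.69 for nlmA, nlmB and SMU.153, and at 0.60 to 0.62 for the named genes of the block from SMU.191c to SMU.217c. Less the trend cclA stood at 3.45, nlmB at 2.54, SMU.196c at 2.60 and SMU.1889c at -2.74.

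Pyrimidine biosynthesis had the lowest list median, at -1.59. Of 13 measured genes 12 fell and 1 rose (camera adjusted p = 0.00244), with adjusted p = 0.689 under an estimated correlation. The neighbours pyrE, pyrF, pyrDB and pyrK (SMU.1221 to SMU.1224), for the last steps to UMP, fell 3.46-fold (-1.79 ± 0.18), 3.68-fold (-1.88 ± 0.26), 4.45-fold (-2.16 ± 0.37) and 4.66-fold (-2.22 ± 0.40), together with the adjacent SMU.1219c, SMU.1220c and the amidase gene nylA, which fell 3.56- to 3.63-fold. Carbamoyl phosphate synthase genes pyrA and carB fell 3.15-fold and 2.98-fold, and pyrC fell 2.21-fold. The untreated channel was saturated on 6 of 8 arrays for carB, 4 for pyrA and 3 for pyrF, so that these folds are compressed. The position trend at the list's genes was -0.44 in the median, and the list median less the trend was -1.19, with pyrC at -0.65.

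Amino acid biosynthesis fell as well. Of 46 measured genes of the list of amino acids other than the branched-chain ones, 37 fell and 3 rose (median -0.74, camera adjusted p = 7.44e-06; adjusted p = 0.689 with an estimated correlation). Among the members named for their small adjusted p, hisC was down 3.31-fold (-1.73 ± 0.08), hisZ 2.94-fold (-1.55 ± 0.04), hisD 2.80-fold (-1.49 ± 0.04) and the adjacent serB, a phosphoserine phosphatase gene, 3.01-fold (-1.59 ± 0.03). In that region 14 adjacent genes from SMU.1260c to SMU.1273 fell, with a median of -1.47, where the trend stood at about -0.47. Branched-chain synthesis had 8 genes lower and 1 higher of 10 (median -0.68, camera adjusted p = 0.0645), and it passed with the position trend subtracted (adjusted p = 0.00379). In it leuA fell 2.55-fold (-1.35 ± 0.11), leuB 2.04-fold, leuC 1.81-fold and ilvE 1.76-fold. Less the trend leuA stood at -0.99, leuB at -0.67, leuC at -0.49 and ilvE at -0.31.

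All 8 genes of the F-type ATPase, the proton-translocating enzyme of the membrane, rose (median 1.13, camera adjusted p = 0.0123; adjusted p = 0.689 with an estimated correlation and 0.168 with all arrays and the replicate as a block). The gene of subunit delta, SMU.1531, rose 3.02-fold (1.59 ± 0.36), atpB (SMU.1533) 2.65-fold (1.41 ± 0.18), SMU.1529 2.28-fold (1.19 ± 0.48) and SMU.1534 2.22-fold (1.15 ± 0.15). The position trend at these genes was -0.19, and SMU.1529 was saturated on 3 of 8 arrays in the carolacton channel.

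**Figure D2:**
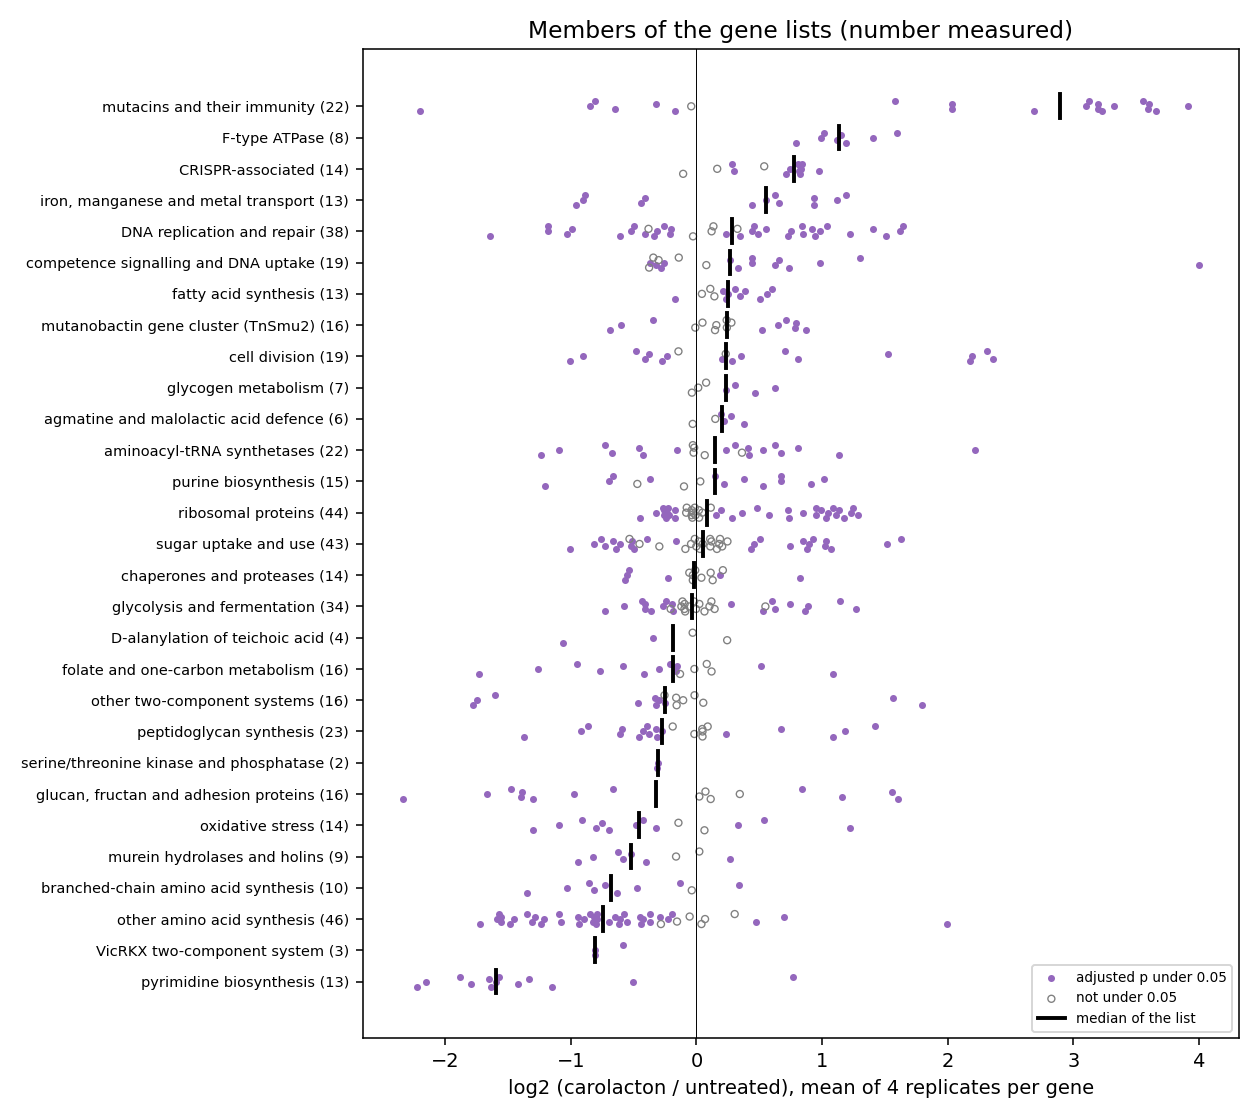
The log2 ratio (x axis, mean of 4 replicates) of each measured member of the 29 gene lists (y axis, number measured in brackets), with filled points for an adjusted p under 0.05, open points for others, and a bar at the list median. The list medians run from -1.59 for pyrimidine biosynthesis to 2.89 for mutacins and their immunity.

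Genes for glucan-mediated adhesion, by which the biofilm matrix holds cells, went both ways. Of 16 measured genes 8 fell and 4 rose (median -0.32, camera adjusted p = 0.481). The glucan-binding protein gene gbpC (SMU.1396) fell 5.06-fold (-2.34 ± 0.13, adjusted p = 4.43e-05) and its neighbour SMU.1395c, above background on 6 of 8 arrays in the carolacton channel, 3.76-fold (-1.91 ± 0.59). The glucosyltransferase genes gtfB and gtfC fell 3.17-fold (-1.66 ± 0.24) and 2.62-fold (-1.39 ± 0.16), whereas gtfD had a log2 ratio of 0.07 ± 0.14 (adjusted p = 0.383). The value of gtfD was -0.06 with median centring (adjusted p = 0.441), -0.17 in the deposited value table (adjusted p = 0.0454) and 0.57 with the position trend subtracted (adjusted p = 0.00107). The sortase gene srtA fell 2.78-fold (-1.48 ± 0.05), and the fructan hydrolase gene fruB rose 3.04-fold (1.60 ± 0.19). Less the trend gtfC stood at -0.82, srtA at -0.90 and fruB at 0.81, and the trend at gtfB was -0.56.

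Among regulators, the genes of the CiaRH two-component system fell: ciaX (SMU.1131c) 5.20-fold (-2.38 ± 0.15), ciaR (SMU.1129) 3.43-fold (-1.78 ± 0.19) and ciaH (SMU.1128) 3.35-fold (-1.74 ± 0.06), where the trend stood at -0.57. The genes hk03 and rr06 (SMU.45 and SMU.46) rose 2.96-fold (1.56 ± 0.18) and 3.47-fold (1.79 ± 0.10), and stood at 0.72 and 0.95 less the trend. Of 16 measured genes of two-component systems other than VicRKX, 8 fell and 2 rose (camera adjusted p = 0.217). The genes vicR, vicK and vicX, of a system that controls cell wall metabolism, fell (log2 ratios -0.80 ± 0.08, -0.81 ± 0.05 and -0.58 ± 0.15), as a list with a camera adjusted p of 0.138. Less the trend vicX stood at -0.38, and vicR was saturated on 3 of 8 arrays in the untreated channel. The serine/threonine kinase gene pknB and the phosphatase gene pppL fell 1.23-fold (-0.30 ± 0.06) and 1.24-fold (-0.31 ± 0.10), and this list of 2 was not tested. The call of pknB ended with separate channels and no pairing (adjusted p = 0.0835). Of the remaining largest falls, the putative transcriptional regulator SMU.921 fell 4.37-fold (-2.13 ± 0.15), SMU.1042 3.93-fold and SMU.620 3.56-fold. Less the trend they stood at -1.63, -1.38 and -1.64.

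Competence genes, for the uptake of DNA, gave 10 rises and 4 falls among 19 measured (median 0.26, camera adjusted p = 0.217). The direction of this list depended on the processing: less the position trend its median was -0.17 and the test pointed downwards (adjusted p = 0.952), and with a strict filter on dim probes it passed upwards (adjusted p = 0.0356). The largest rise of this list was that of cclA (SMU.1904c), described above with the mutacin region, at 16.01-fold and a log2 ratio of 3.45 less the trend. The alternative sigma factor gene comX rose 2.46-fold (1.30 ± 0.10) and the signal peptide, sensor kinase and regulator genes comC, comD and comE rose 1.58-fold (0.66 ± 0.23), 1.67-fold (0.74 ± 0.29) and 1.55-fold (0.63 ± 0.30). With the position trend subtracted, comX stood at 0.62, and comC, comD and comE at 0.09, 0.17 and 0.06, not past the threshold. The genes cinA and coiA rose 1.98-fold and 1.35-fold, and stood at 0.18 and 0.66 less the trend. With the deposited value table and the scanner's processed signals, comX stood at 0.86 and 2.05 and coiA at 0.23 and 0.91.

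Cell division and cell wall genes moved in both directions. Of 19 cell division genes 10 rose and 7 fell (camera adjusted p = 0.326). SMU.11 (coordinates 9482 to 9601), which the list held as the septum gene divIC, rose 4.97-fold (2.31 ± 0.23). The array annotates it only as a hypothetical protein, so its identity as divIC is uncertain. The shape gene mreD rose 4.57-fold (2.19 ± 0.31). The gene mnmG, a tRNA modification gene that the list held under an older name, rose 4.53-fold (2.18 ± 0.10). Less the trend SMU.11, mreD and mnmG stood at 1.42, 1.32 and 1.31. The gene ftsE, saturated on 4 of 8 arrays in the untreated channel, fell 2.01-fold (-1.01 ± 0.04, and -0.58 less the trend). The gene ftsZ had a log2 ratio of -0.14 ± 0.08 (adjusted p = 0.0544), and divIVA rose 1.15-fold (adjusted p = 0.0436), a call lost in the fit of all arrays with the replicate as a block (adjusted p = 0.187) and when any 1 replicate was left out. In the deposited value table divIVA stood at -0.01 and ftsZ at -0.22, past the threshold (adjusted p = 0.0245). Also past it ftsZ stood at -0.20 on the arrays with carolacton in Cy3 alone (adjusted p = 0.00974), at -0.17 without replicate 2 (adjusted p = 0.0487) and at an adjusted p of 0.0498 with no background correction, 0.0396 with a robust and trended prior variance and 0.0143 with 8 arrays taken as independent, and less the trend it stood at -0.04. Both channels of ftsZ and divIVA were saturated on 3 or 4 of 8 arrays. Of 23 peptidoglycan genes 12 fell and 5 rose (camera adjusted p = 0.364). The ligase gene ddl fell 2.59-fold (-1.37 ± 0.10), murF 1.89-fold and murB 1.82-fold, and the penicillin-binding protein gene pbp2a rose 2.13-fold. Less the trend murB stood at -0.33 and pbp2a at 0.48. Of 9 genes of murein hydrolases and holins 6 fell and 1, SMU.836, rose 1.21-fold (camera adjusted p = 0.217). SMU.836 was above background on 5 of 8 arrays in the carolacton channel and 4 of 8 in the untreated channel. It stood at 0.12 in the deposited value table, at 0.70 less the trend and at 0.56 with the scanner's processed signals. The autolysin gene atlA fell (log2 ratio -0.59 ± 0.11), SMU.704c 1.92-fold and SMU.707c 1.77-fold, and less the trend atlA stood at -0.30 and SMU.707c at -0.53. In the dlt operon for D-alanylation of teichoic acid, dltA fell 2.09-fold (-1.07 ± 0.17) and dltB 1.27-fold, while dltC and dltD stood at -0.03 ± 0.29 and 0.24 ± 0.33 and did not pass (camera adjusted p = 0.51). Without replicate 1, dltC stood at 0.11 (adjusted p = 0.133) and dltD at 0.41 (adjusted p = 0.00196).

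Folate and one-carbon genes gave 10 falls and 2 rises among 16 measured (median -0.19, camera adjusted p = 0.217), and the median less the trend was 0.08. The formate-tetrahydrofolate ligase gene fhs fell 3.31-fold (-1.73 ± 0.14), folC 2.39-fold (-1.26 ± 0.15) and folE 1.93-fold, and metC rose 2.13-fold. Less the trend fhs stood at -1.12, folC at -0.72 and folE at -0.42. The gene folD, of the bifunctional dehydrogenase and cyclohydrolase of the folate cycle, fell 1.11-fold (-0.15 ± 0.02, adjusted p = 0.0277). It stood at -0.01 with the trend subtracted, which was not past the threshold, and its call ended without replicate 3 or replicate 4 (adjusted p = 0.144 and 0.121) and with separate channels and no pairing (adjusted p = 0.219). Purine biosynthesis gave 8 rises and 4 falls among 15 (camera adjusted p = 0.44). In it guaA fell 2.31-fold (-0.60 less the trend), and purA and purB rose 1.60-fold and 2.03-fold, where the trend stood at 0.51 and 0.83. Less the trend purA stood at 0.16 and purB at 0.19, the latter not past the threshold. With the trend subtracted the median of this list turned from 0.15 to -0.60 (camera adjusted p = 0.0407). Its member prsA, which fell 1.58-fold, is the gene of a foldase, not of a purine enzyme. It was saturated on 4 of 8 arrays in the untreated channel and stood at -0.43 less the trend.

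Genes for DNA replication and repair gave 19 rises and 14 falls among 38 measured (camera adjusted p = 0.221). The gyrase genes gyrA and gyrB fell 3.12-fold (-1.64 ± 0.17) and 2.27-fold (-1.18 ± 0.05), the mismatch repair gene mutL rose 3.13-fold (1.65 ± 0.06) and ruvB rose 1.80-fold (0.85 ± 0.03). With the trend subtracted, gyrA stood at -1.06, gyrB at -0.72, mutL at 0.83 and ruvB at 0.02, the last not past the threshold. Of 44 ribosomal protein genes 21 rose and 11 fell (camera adjusted p = 0.155), with rplR up 2.43-fold, rplI 2.38-fold, rpsN 2.20-fold and rpsE 1.80-fold at trend values of 0.70 to 0.87. Less the trend rplR stood at 0.58, rplI at 0.38, rpsN at 0.43 and rpsE at 0.15, the last not past the threshold. The carolacton channel was saturated on 4 of 8 arrays for rplR, 3 for rplI and 5 for rpsE. This list passed camera with median centring in place of loess (adjusted p = 0.00143), with the scanner's processed signals (adjusted p = 0.0156) and on the arrays with carolacton in Cy5 alone (adjusted p = 0.0195), and its median was 0.08. Of 22 aminoacyl-tRNA synthetase genes 10 rose and 7 fell (camera adjusted p = 0.51). The cysteinyl-tRNA synthetase gene cysS rose 4.65-fold (2.22 ± 0.40) and trpS 2.19-fold, while lysS fell 2.36-fold (-1.24 ± 0.06) and alaS 2.13-fold. Less the trend cysS stood at 1.54, trpS at 0.24, lysS at -0.87 and alaS at -0.86.

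In energy metabolism and stress, the groups were mixed. Of 34 glycolysis and fermentation genes 9 rose and 10 fell (camera adjusted p = 0.818), and the pyruvate dehydrogenase genes pdhA, pdhB and lpdA (SMU.1424) rose 1.82-fold, 1.85-fold and 2.20-fold (1.14 ± 0.18) and adh rose 2.41-fold (0.53 less the trend). The sizes for the pyruvate dehydrogenase genes varied with the processing. The log2 ratios of pdhA, pdhB and lpdA were 0.45, 0.52 and 0.60 in the deposited value table and 2.37, 1.85 and 2.96 with the scanner's processed signals, and their untreated channel was above background on 4, 6 and 6 of 8 arrays. Of 43 sugar uptake genes 13 rose and 12 fell (camera adjusted p = 0.298). The sucrose transporter gene scrA rose 3.09-fold (1.63 ± 0.12) and its regulator gene scrR 2.10-fold, with treP up 1.87-fold and malX up 1.80-fold. Less the trend scrR stood at 0.62. The gene treP stood at 0.16 less the trend (adjusted p = 0.0432) and at 1.65 with its brightest probe, its probes lay 1.18 apart, and its call ended with separate channels and no pairing (adjusted p = 0.0547). Of 7 glycogen genes 4 rose, glgP (SMU.1564) 1.54-fold, glgA 1.38-fold, glgD 1.24-fold and glgC 1.17-fold (camera adjusted p = 0.217). The calls of glgC and glgD ended with median centring (adjusted p = 0.27 and 0.11), that of glgC also when any 1 replicate was left out, and that of glgD without replicate 3 (adjusted p = 0.0551). With the position trend subtracted glgC and glgD stood at 0.41 and 0.49 and the list passed (adjusted p = 0.0181), while both calls ended with separate channels and no pairing (adjusted p = 0.397 and 0.139) and in the deposited value table (adjusted p = 0.93 and 0.369). Of 14 oxidative stress genes 9 fell and 3 rose (median -0.46, camera adjusted p = 0.217). The thiol peroxidase gene tpx fell 2.47-fold (-1.30 ± 0.15), nox 2.14-fold (-1.10 ± 0.09) and spx (SMU.1142c) 1.68-fold, while the glutathione synthesis gene gshAB rose 2.33-fold (1.22 ± 0.14). Less the trend tpx stood at -0.80, nox at -0.52, spx at -0.19 and gshAB at 0.70. Of 14 chaperone and protease genes 4 fell and 2 rose, with clpE down 1.48-fold, clpX 1.45-fold and clpP 1.17-fold and hslO up 1.77-fold (camera adjusted p = 0.967). The call of clpE, saturated on 5 of 8 arrays in the untreated channel, ended in the fit of all arrays with the replicate as a block (adjusted p = 0.279) and on the arrays with carolacton in Cy5 alone (adjusted p = 0.0597), and clpX stood at -0.02 with the position trend subtracted, not past the threshold, and hslO at 0.19. The call of clpP ended on the arrays with carolacton in Cy5 alone (-0.05, adjusted p = 0.456) and without replicate 3 (adjusted p = 0.0594). With the trend subtracted the list median was -0.60 (camera adjusted p = 0.0173). The co-chaperonin gene groES was saturated on 8 of 8 arrays in the carolacton channel and 7 of 8 in the untreated channel. Its ratio (-0.03) is compressed, and its -0.65 less the trend mostly reflects the trend of 0.62 subtracted.

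The other lists were tested with these results. Of 14 CRISPR-associated genes 11 rose (median 0.78, camera adjusted p = 0.0689), among them cas8c 1.97-fold (0.98 ± 0.61), SMU.1762c 1.77-fold, cas5c 1.68-fold and cas2 (SMU.1403c) 1.23-fold. The list passed without replicate 2 (adjusted p = 0.0198) and with the position trend subtracted (adjusted p = 0.00949), while calls of its members ended when replicates were left out. Those of cas2 and SMU.1762c ended in 2 of 4 such fits (highest adjusted p = 0.0834 and 0.0667) and that of cas5c in 3 of 4 (highest adjusted p = 0.103). Less the trend cas2 stood at 0.64 and cas5c at 0.52, the latter not past the threshold, and the call of cas2 ended with separate channels and no pairing (adjusted p = 0.109), with median centring (adjusted p = 0.107) and in the deposited value table (adjusted p = 0.374). Of 13 fatty acid synthesis genes 9 rose and 1 fell (camera adjusted p = 0.0744), with accA up 1.51-fold, acpP (SMU.27) 1.48-fold, accD 1.42-fold and fabM 1.31-fold. This list passed with median centring in place of loess (adjusted p = 0.00413), with the scanner's processed signals (adjusted p = 0.0236) and on the arrays with carolacton in Cy5 alone (adjusted p = 0.00577). Less the trend its median was 0.08 in place of 0.25 (adjusted p = 0.489) and fabM stood at 0.21. The gene acpP was saturated on 3 of 8 arrays in the carolacton channel, and the call of accD ended with the replicate as a block (adjusted p = 0.111) and in the deposited value table (adjusted p = 0.0836). On the arrays with carolacton in Cy3 alone, accA stood at 0.39 and accD at 0.25, not past the threshold. Of 13 metal transport genes 8 rose and 5 fell (camera adjusted p = 0.364), with sloR up 1.92-fold, zupT up 1.54-fold, the copper chaperone gene copZ down 1.94-fold and feoA down 1.36-fold. Less the trend sloR stood at 0.30, and copZ was saturated on 3 of 8 arrays in the untreated channel. Of 16 genes of the mutanobactin cluster 6 rose and 3 fell (camera adjusted p = 0.221), with mubG up 1.74-fold, mubT up 1.64-fold and mubR down 1.52-fold. Their neighbour mubY fell 1.61-fold, which is uncertain because it shares a probe sequence with another gene and its untreated channel was saturated on 5 of 8 arrays. Its call ended with the replicate as a block (adjusted p = 0.114), and it stood at -0.30 less the trend. Less the position trend mubG stood at 1.19 and mubR at -0.22, the latter not past the threshold, the trend at mubT was -0.39, and the list passed (adjusted p = 0.00307). Of 6 acid defence genes 4 rose, mleP 1.30-fold, mleS 1.21-fold, aguC 1.16-fold and aguD 1.14-fold (camera adjusted p = 0.217). With the trend subtracted these 4, and also acpP and zupT, fell below 0, mleP to -0.33, mleS to -0.44, aguC to -0.30, aguD to -0.33, acpP to -0.30 and zupT to -0.17, each past the threshold. The calls of aguC and aguD also ended without replicate 3 or replicate 4 (highest adjusted p = 0.0553 and 0.0712) and on the arrays with carolacton in Cy5 alone (adjusted p = 0.145 and 0.119), and that of mleS without replicate 1, 3 or 4 (highest adjusted p = 0.0902). With separate channels and no pairing those of mleP and mleS ended (adjusted p = 0.257 and 0.351), and in the deposited value table those of mleS, aguC and aguD (adjusted p = 0.377, 0.0781 and 0.0961). Across the alternatives other than leaving out a replicate, the log2 ratio reached 0.55 for aguC and 0.48 for aguD at the highest.

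Across the 28 lists tested, 4 passed with the preset correlation and 0 with an estimated correlation, where the adjusted p ran from 0.689 to 0.968. That estimate rests on 4 replicates. Less the position trend, medians that turned were those of metal transport (0.55 to -0.17), aminoacyl-tRNA synthetases (0.15 to -0.13), agmatine and malolactic acid defence (0.21 to -0.36), glycolysis and fermentation (-0.04 to 0.05) and sugar uptake (0.05 to -0.03), besides those of competence, folate and purine genes. The medians of DNA replication and repair (0.28 to 0.04) and oxidative stress (-0.46 to -0.29) shrank, and those of two-component systems other than VicRKX (-0.25 to -0.49), glycogen metabolism (0.23 to 0.41) and mutanobactin (0.24 to 0.66) grew. With fry, which tests whether the genes of a list move one way on balance without comparing them with other genes, 22 lists passed. Counts of changed members adjusted over the list alone were the same as over all genes in 26 of the 29 lists. They were 11 higher and 8 lower for cell division, 3 higher for glycogen metabolism, and 9 higher and 8 lower for glycolysis and fermentation. Signs differed for chaperones and proteases (median -0.02, mean -0.04, camera upwards, fry downwards), for glycolysis and fermentation (median -0.04, mean 0.10, both tests upwards) and for aminoacyl-tRNA synthetases (median 0.15, camera upwards, fry downwards).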

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

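Of the tests here, those of genomic DNA, array place, GC content and gene groups, and the sign turns and splits, were set before their results were seen. Those of dye or single array, dosage, hybridisation noise, mixtures, untreated cultures, and both for the block from SMU.191c to SMU.217c were chosen after related values had been seen.

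The log2 ratio fell with distance from the replication origin, by a line of slope -1.65 per Mb that took up 29.7% of the variance across genes. Genomic DNA carried over with the RNA would weigh most in dim genes. Split into 3 parts by intensity, the dimmest genes had a slope of -1.31 per Mb, the middle ones -2.06 and the brightest -1.71. The slope of the brightest was 1.30 times that of the dimmest. Unspecific signal, seen in the negative controls, also compresses the ratios of dim genes, so these slopes do not decide on genomic DNA. The flattest of the 4 equal parts of the printed array kept 0.94 of the steepest slope, and adjustment for probe GC content kept 0.997 of the slope. The 592 hypothetical genes in no list had 1.02 times the slope of all genes. They are not free of clusters by position, since the block from SMU.191c to SMU.217c holds hypothetical genes. Without this block the slope of all genes was -1.53 per Mb. The flattest of 8 arrays kept 0.764 of the steepest slope. A hypothesis is that gene dosage between origin and terminus differed between treated and untreated cells, as it may where DNA replication or growth differs; both arms fell, the flatter with 0.96 of the steeper slope, but DNA content and growth were not measured here and this stays untested.

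Replicates 1 and 2 lay farthest apart. In 128 genes they differed by over 1 on the log2 scale, and replicate 3 lay between them in 95.3% of these and replicate 4 in 96.1%. Hybridisation noise of single arrays is argued against, since the differences recurred in the other dye orientation with r = 0.893 across genes, which are not independent replicates. Both arrays of a replicate lay in the same column of the slide, so an effect of the column cannot be told apart from a difference between replicates. Mixtures of the RNA of replicates 1 and 2 stay open: replicates 3 and 4 correlated at 0.991 across genes, a fit on replicates 1 and 2 left 4.31% and 4.28% of their variance, and what was left recurred between orientations with r = 0.881 and 0.855, but so did what was left of an equal mixture computed from the arrays (r = 0.716). The untreated RNA of replicates 1 and 2 differed 1.76 times as much as the carolacton RNA (SD 0.647 against 0.367), so differing untreated cultures may account for part of the spread, a hypothesis found on these data.

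The 24 genes from SMU.191c to SMU.217c rose by 2.57 more than the median of the 92 genes within 50 kb, so the position trend does not account for the block. All 64 of its probes (100%) showed at least 50% of its median, against cross-hybridisation of few probes. A change in transcription and a change in copy number of this region may both give such a block, and neither was tested, since DNA was not measured.

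In 10 of 144 named genes 1 replicate stood apart from the other 3, where chance picks about 1 in 20; 6 were replicate 1 and 4 replicate 2. In replicate 1, the log2 ratio of SMU.1395c was -2.79 (others -1.70 to -1.48), of aguD 0.24 (0.18 in the others), of ilvE -0.59 (-0.92 to -0.87), of clpE -1.0 (-0.47 to -0.37), of dltD -0.25 (0.37 to 0.44) and of scrR 1.32 (0.97 to 1.02). In replicate 2, it was 2.67 for mreD (others 2.02 to 2.05), 1.02 for accA (0.42 to 0.48), 0.71 for glgA (0.36 to 0.40) and 0.58 for glgD (0.18 to 0.24).

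Among the arrays with carolacton in Cy5, replicate 1 had 79.4% of spots above background in Cy3 (others 91.2 to 92.1%) and 83.1% in Cy5 (92.5 to 92.8%). Among those with carolacton in Cy3, replicate 1 had a negative control signal of 834 in Cy5 (others 1080 to 1110) and replicate 2 had 8.97% saturated spots in Cy5 (11.3 to 11.7%). The dye orientations differed in 767 genes by the limma test of the dye effect, with a median absolute dye effect of 0.04 against a median absolute log2 ratio of 0.51; in 12 changed genes the dye effect was the larger. Of 624 probes between genes, which no comparison above used, 452 changed.

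Turning the sign of whole replicates gives 8 arrangements, too few for a share under 0.05; the real one, 1 of the 8, gave 1447 genes and the highest other 0. With separate channels, the real one (1) of the 35 splits of the 8 RNA samples gave 1187 genes and the highest other gave 0. Every other split mixes carolacton with untreated RNA in both groups, so a large treatment difference widens the spread within them. Of the 35 splits, 8 part all 4 pairs as the real one does, and the highest other among them gave 0. As the samples are paired, only these 8 compare like with like, too few to decide on chance.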

How the results depend on the processing

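The alternatives with the position trend subtracted and without the dimmest array were chosen after seeing the data. The count of changed genes ran from 1167 at a threshold of 0.01 to 1599 with 8 arrays taken as independent, and stayed within 1.5 times 1447 throughout. The count at 2-fold ran from 267 with the trend subtracted to 483 with the scanner's processed signals. Of 3438 values of named genes under alternatives, 3331 kept direction and side of the threshold, 89 were no longer past it, 8 came past it and 10 reversed. The slide could not be run as a block, since all arrays share 1 slide. In the paired fit of all arrays with the replicate as a block 1384 genes changed, and among named genes and lists the calls of clpE (-0.57), accD (0.51), mubY (-0.69), divIVA (0.20) and the F-type ATPase list (1.13) ended and no other changed; the cause was not tested. The dim array, saturated spots and negative control signals of 834 to 1390 limit what faint and bright genes can show.

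In the deposited value table gtfD reversed to -0.17 and divIVA to -0.0060, and with median centring gtfD to -0.064. The value of dltC ran from -0.11 to 0.11 with 1 replicate left out. With the position trend subtracted, mleP (-0.33), aguC (-0.30), aguD (-0.33), mleS (-0.44), acpP (-0.30) and zupT (-0.17) reversed, as did the lists of agmatine and malolactic acid defence (-0.36), chaperones and proteases (-0.60) and purine biosynthesis (-0.60), and, not past the threshold, aminoacyl-tRNA synthetases (-0.13), competence (-0.17), metal transport (-0.17) and folate (0.083); except for folate, subtracting a trend that is positive there accounts for these. With fry, the test turned downwards for chaperones and proteases (median -0.019) and aminoacyl-tRNA synthetases (0.15). For chaperones and proteases, whose test pointed upwards at a median of -0.019, it also turned with the brightest probe (-0.033), on the arrays with carolacton in Cy3 alone (0.011), in the deposited value table (-0.098), without the dimmest array (-0.0060) and without replicate 1 (medians from -0.031 to -0.0095 with 1 replicate left out), and that of glycolysis and fermentation turned with the strict filter (-0.090). Of the gene list tests, 2 lists passed at 0.01, 11 with the trend subtracted, 0 with an estimated correlation and 22 with fry, against 4. The dye effect was called in 1656 genes with median centring, which leaves intensity-dependent dye bias in, and in 156 to 1140 genes with 1 replicate left out (1140 without replicate 1, 443 without 2, 209 without 3 and 156 without 4), against 767. For the other reversals and shifts the cause was not tested.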

Other observations

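None of the values in this part were tested against an explanation, and the probes and regions named here were chosen after their values were seen. Of 624 probes between genes that passed the filter, 222 rose and 230 fell, and 106 changed at least 2-fold, 66 higher and 40 lower. The probe at 926363 to 926534, between bglP and bglB1, had a log2 ratio of 3.74, with -0.16 for bglP and 2.05 for bglB1. The probe at 741066 to 741645, between SMU.789 and SMU.790, stood at 3.22 while its neighbours stood at -0.61 and -0.58, and the probe at 1376970 to 1377079, between SMU.1446c and trpX, stood at 3.08 with neighbours at -0.66 and -0.84. The probes between genes fell with distance from the origin too, with a Spearman rho of -0.48 across probes.

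Runs of at least 4 adjacent genes on 1 strand that changed at least 2-fold the same way numbered 18, with 135 genes, of which 12 runs rose and 6 fell. Besides those in the report, 9 genes from tagI to SMU.2096c, with mutL and mutS, rose with a median of 1.48, 7 genes from pth to tilS rose with a median of 1.75, and 6 genes from SMU.156 to SMU.161, with cysE and cysS, rose with a median of 2.28. The 5 genes from opuBc to SMU.1100c fell with a median of -1.38 and the 4 genes from SMU.1037c to SMU.1040c, with phoR, with a median of -1.49.

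Of 18 probes for sequences of other organisms, the 3 for the red fluorescent protein DsRed were well above background on 7 of 8 arrays in each channel, at log2 ratios of 0.13 to 0.17, and 1 for the Evoglow protein on 5 arrays in the carolacton channel and 7 in the untreated channel. The other 14 were on none.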
